A study of Mus musculus with 93 samples.

How the data were processed

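RNA-seq of mouse liver was re-analysed from 93 libraries of heterozygous Htt knock-in mice (alleles Q20, Q50, Q92 and Q140) and wild-type controls at 6 and 10 months, both sexes. Per the labels' protocols, total RNA was taken from flash-frozen tissue with the miRNeasy kit and libraries followed standard Illumina protocols. The labels name the mice each animal was housed with; a housing label is called a colony or housing group here, and it says nothing more about breeding. The labels number the replicates within each group but do not say separately that each is a different mouse, so p-values measure the spread between these libraries. A strand setting is not given in the sources used here, nor are the aligner, counter, genome build and annotation.

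The deposited expected counts per Ensembl gene are estimated numbers of reads, and 26.0% of the values above 0 were not whole (tolerance 0.001). The deposited FPKM values were scaled by the authors to the length of each gene and to the fragments of each library. CASAVA 1.8.2 is the tool named in the submitters' processing notes. Each table held 39179 genes and 93 columns, all of which matched a labelled sample, and symbols were found for 37607 identifiers, leaving 1572 without. Gene positions and biotypes came from the GENCODE annotation of GRCm38, joined on the Ensembl identifier. Total counts per library ran from 28752184 to 46776898, the 10 most abundant genes of a library took 17.2% to 29.7% of its counts, and mitochondrial transcripts took 7.6% to 26.8%. No pair of libraries was identical. Over genes with at least 50 counts, pairs of replicates differed by a chi-square of 25.4 to 581 per degree of freedom (135 pairs within groups).

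Expected counts were rounded first and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 24 groups (minimum count 10, minimum total 15), which left 16126. Libraries were scaled by TMM (factors 0.847 to 1.156). A negative binomial model with 1 mean per group (genotype or wild-type colony, by sex, by age) was fitted to all 93 libraries with estimateDisp and glmQLFit with robust estimation (median prior degrees of freedom 5.08). Contrasts, averaging the sexes with equal weight, were tested with glmQLFTest at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. The standard error of a log2 difference was taken as the difference divided by the square root of its F statistic. Each allele of short repeat was compared with wild types of its housing, Q92 and Q140 with Q20 because the labels give them no wild types, and a linear contrast in CAG length was scaled to the change from 20 to 140. Housing groups of wild types, ages, sexes, and the dependence of Q140 against Q20 on sex and age were further contrasts. CPM values use the TMM-scaled library sizes, except for the brain transcripts and mitochondrial shares, which use total counts.

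For lists of genes, 37 lists written in advance were tested in 16 contrasts with limma 3.58.1's camera on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists of a contrast, and beside it with an estimated correlation and with fry. Of the 592 tests 212 passed with the preset and 8 of these held with an estimated correlation. Counts of list members are given over all genes tested and adjusted over the list alone. The comparisons, the lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Htt in every comparison; up to 10 genes that rose and 10 that fell with the largest change, at adjusted p under 0.05 and a mean of at least 1 CPM, for the comparisons with Q20, the trend, age and sex, and up to 5 and 5 for the others; up to 4 members with the smallest p per list described; and, where no gene passed, the 3 with the smallest p. Genes without a symbol were skipped. Calls outside this rule (Gm2445, Hoxa5, Serpinb1c and 1 identifier without symbol, all below 1 CPM on average or without a symbol) are named where a count is small, and Atraid, Pisd and Prr14l were named from a contrast of Q20 and Q50 against wild types over both ages; all these were chosen after their values were seen.

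The alternatives were DESeq2 1.42.0 (Wald test, its own size factors and independent filtering), RLE factors, no filter on low counts, the replicate number as a block, a separate fit per age, limma with trend on log2(FPKM + 0.1) and log2(FPKM + 1) with a mean FPKM of at least 0.1, the former also without a filter, 3 surrogate variables from sva 3.50.0, the lane of the label as a covariate within each age, omission of the 16 libraries without an index in their label (5 of 48 at 6 months and 11 of 45 at 10 months), other reference groups, and omission of each library in turn. For the lane covariate the libraries without an index were pooled as a level of their own, whatever their lane, so it also adjusts for the missing index. The omissions of each library in turn and 100 other splits of the samples per comparison kept the trended dispersion of the full fit and re-estimated the quasi-likelihood dispersions, a shortcut taken for run time. After the data were examined, 4 further choices were made: the trend without each CAG length in turn, the contrast of Q20 and Q50 together, a coding of the lane that sums to 0 within each age, and the omission of 5 libraries. Of these 5, 4 had a sum over 12 brain transcripts above 3 times the median of 7.3 CPM and 2 had a mitochondrial share above 1.5 times the median of 9.36%; the brain genes and both limits were chosen after library values were seen, and no library was left out of the values in the report.

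The procedure was tested on simulated data: counts drawn from the real means and library sizes with 200 genes changed between Q92 and Q20 at 10 months. Among 16126 genes edgeR recovered 80.6% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 12 false calls. With limma the shares were 85.1%, 92.5% and 98.5% with 9 false calls, and with DESeq2 88.1%, 91.0% and 98.5% with 12 false calls of 14249 genes tested. Counts were drawn for each gene on its own, so differences that many genes of a library share were not simulated. Only genes with a mean of at least 1 CPM were changed. In the real samples a split other than the real one called up to 95 genes for this comparison, so the false calls above do not bound those in the real data. The random seed was 1. Results of some single genes are not reported here.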

Results

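Liver RNA was sequenced in 93 libraries from C57BL/6 mice of a Huntington's disease knock-in series, in which 1 copy of the huntingtin gene Htt carries a lengthened CAG repeat. The alleles are named Q20, Q50, Q92 and Q140, for CAG lengths of 20, 50, 92 and 140. Wild-type controls, described by the submitters as littermates, were labelled as housed with Q20 or with Q50 heterozygotes, and no wild-type library was labelled as housed with Q92 or Q140 mice. Genotype, housing, sex and age (6 or 10 months) made 24 groups, 21 of 4 libraries and 3 of 3 (Q20, Q92 and Q140 males at 10 months). Total counts per library ran from 28752184 to 46776898 (median 36089384), and the libraries of 10 months had a median of 34378533. Expression is given in CPM (counts scaled to library size) as mean ± SD, with n = 8 libraries per genotype and age, or 7 for Q20, Q92 and Q140 at 10 months. Log2 differences average both sexes, carry their standard error and come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16126 genes.

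The targeted gene Htt (ENSMUSG00000029104, chromosome 5) was measured in every genotype. Its level was 33.8 ± 4.83 CPM in Q20, 29.8 ± 5.05 in Q50, 25.97 ± 3.72 in Q92 and 26.8 ± 2.93 in Q140 mice at 6 months. Wild types of that age had 30.7 ± 5.84 CPM when housed with Q20 and 32.5 ± 7.24 CPM when housed with Q50 mice. At 10 months it was 35.3 ± 2.93 in Q20, 30.01 ± 4.82 in Q50, 28.2 ± 3.45 in Q92 and 24.2 ± 6.30 in Q140 mice. The respective wild types had 34.5 ± 3.78 and 32.5 ± 5.21 CPM. Htt was lower in Q140 than in Q20 mice at 10 months (log2 difference -0.53 ± 0.10, adjusted p = 0.0137). At 6 months the difference of -0.33 ± 0.10 did not pass (adjusted p = 0.13), and the change of the difference with age was -0.21 ± 0.14 (adjusted p = 0.607). Q92 against Q20 gave -0.37 ± 0.10 (adjusted p = 0.159) at 6 and -0.31 ± 0.10 (adjusted p = 0.0791) at 10 months. Along the CAG length from Q20 to Q140, Htt fell by 0.49 ± 0.10 on the log2 scale at 10 months (adjusted p = 0.0186). The fitted change of -0.33 ± 0.09 at 6 months did not pass (adjusted p = 0.115). Q20 and Q50 did not differ detectably from their wild types (Q20 0.13 ± 0.10 and 0.04 ± 0.10, Q50 -0.12 ± 0.10 at each age). Among Q140 mice at 10 months the 4 females had 19.8 ± 4.45 CPM and the 3 males 30 ± 0.923 CPM. Q20 females and males of that age had 35.6 ± 1.16 and 35 ± 4.84 CPM. At 6 months Q140 females and males had 27.1 ± 3.09 and 26.5 ± 3.19 CPM, against 30.9 ± 3.7 and 36.6 ± 4.32 CPM in Q20. The means thus lay further apart in females at 10 months and in males at 6 months. The difference between the sexes in Q140 against Q20 over both ages was 0.17 ± 0.14 (adjusted p = 0.821). That value averages the ages, and the sexes were not tested at 10 months alone. The 10-month call for Q140 was absent on the FPKM scale (-0.41) and without the libraries that carry no index in their label (-0.38). The 10-month trend was no longer past the threshold without replicate 3 of the Q140 males (-0.50) or replicate 4 of the Q20 females (-0.48). It was also not past it on the FPKM scale (-0.36), without the libraries lacking an index (-0.35), without Q20 (-0.39) or without Q140 mice (-0.50). Calls were gained as well, by DESeq2 for the trend at 6 months (-0.34) and with 3 surrogate variables for that trend (-0.32), for Q140 at 6 months (-0.33) and for Q92 at 10 months (-0.35). Q92 at 10 months also passed without the 5 libraries with brain transcripts or a high mitochondrial share (-0.31), none of which is in those groups.

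Does the knock-in allele with a short repeat change the liver? In Q20 mice against wild types of the same housing, Abhd1 was the 1 gene that passed at each age. Abhd1 (ENSMUSG00000006638) is named for the alpha/beta hydrolase family and lies 3.8 Mb from Htt on chromosome 5. The annotation used here records it as a processed transcript, not as protein coding. It stood at 23.7 ± 1.38 CPM in Q20 against 1.70 ± 0.476 in wild-type mice at 6 months (log2 difference 3.80 ± 0.20, adjusted p = 2.07e-25). At 10 months the levels were 22.4 ± 2.09 and 2.09 ± 0.773 CPM (3.44 ± 0.20, adjusted p = 8.88e-23). At an unadjusted p under 0.05 there were 1921 genes at 10 months, while at 6 months there were fewer than chance alone gives among the genes tested. Without replicate 3 of the wild-type males housed with Q20 at 10 months 11 genes passed, without replicate 2 of the wild-type females 4, and without replicate 1 of the Q20 males 2. At 6 months 2 genes passed without replicate 4 of the Q20 males.

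The Q50 allele gave the same leading gene. Abhd1 was at 19.4 ± 7.11 CPM in Q50 and 1.74 ± 0.435 in wild-type mice at 6 months (3.47 ± 0.20, adjusted p = 3.02e-23). It was at 20.2 ± 1.41 and 1.88 ± 0.332 CPM at 10 months (3.42 ± 0.20, adjusted p = 4.96e-23). At 10 months Galnt11, a transferase that starts the O-linked glycosylation of proteins, was also higher (16.7 ± 1.65 against 11.1 ± 0.984 CPM, 0.59 ± 0.10, adjusted p = 0.000891). No other gene passed at either age, with 361 and 373 genes at an unadjusted p under 0.05. Abhd1 was equally high with the long repeats, with 23.1 and 20.8 CPM in Q92 and 21.3 and 20.0 CPM in Q140 mice at 6 and 10 months. It did not change detectably along the CAG length (-0.05 ± 0.16 and -0.13 ± 0.17). A single knock-in library departed from this, replicate 1 of the Q50 females at 6 months, with 99 counts of Abhd1 or 2.39 CPM. A wrong label of this library was not excluded, and it stayed in the Q50 means and tests; without it the Abhd1 difference of Q50 at 6 months was 3.64. Abhd1 overlaps Preb in the reference annotation, and without strand information in the labels their shared reads cannot be assigned with certainty. The Galnt11 call at 10 months was lost without the libraries lacking an index, at a log2 difference of 0.60.

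**Figure D1:**
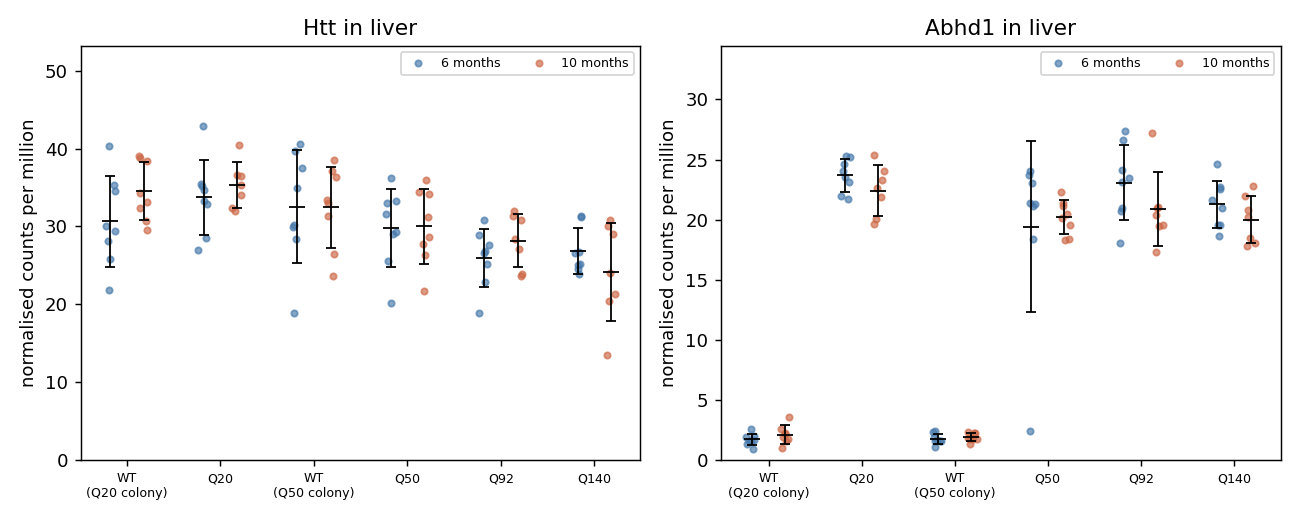
Htt and Abhd1 by genotype and age, in CPM on the vertical axis; points are libraries, and bars are the mean with 1 SD. Abhd1 stands near 20 CPM in the knock-in groups and near 2 CPM in the wild types, apart from 1 Q50 library at 2.39 CPM.

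Genes around Htt were then compared between all 31 Q20 and Q50 libraries and their 32 wild types, a comparison chosen after the Abhd1 difference was seen. The 5 genes that passed all lay on chromosome 5. Abhd1 (3.53 ± 0.10, adjusted p = 3.7e-43), Galnt11 (0.26 ± 0.05, adjusted p = 0.0129) and Prr14l (0.21 ± 0.04, adjusted p = 0.0211) were higher in knock-in mice. So was Pisd (0.24 ± 0.04, adjusted p = 0.000156), whose enzyme makes phosphatidylethanolamine in mitochondria. Atraid was lower (-0.24 ± 0.03, adjusted p = 1.06e-07). Htt itself was at -0.02 ± 0.05 (adjusted p = 0.965). Over both ages Galnt11 was at 11.3 ± 1.42 CPM in Q20 mice (n = 15), close to 11.4 ± 1.8 and 11.3 ± 1.28 CPM in the wild types (n = 16 each). It was at 16.2 ± 2.02 CPM in Q50 (n = 16), 15.3 ± 2.80 in Q92 and 16.1 ± 3.87 in Q140 mice (n = 15 each). Leaving out Htt and Abhd1, 26 of 139 tested genes within 10 Mb of Htt had an unadjusted p under 0.05, or 18.7%. Of the other 15985 genes 5.6% had one (odds ratio 3.89, 95% interval 2.42 to 6.03, Fisher's exact test, two-sided p = 7e-08). That test counts neighbouring genes as independent, so its p and interval do not measure the spread between libraries. Galnt11, Atraid, Pisd and Prr14l each overlap another annotated gene, so a share of their reads is uncertain. Positions are those of the GRCm38 annotation for the same gene identifiers, since the build behind the counts is not given in the sources used here.

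**Figure D2:**
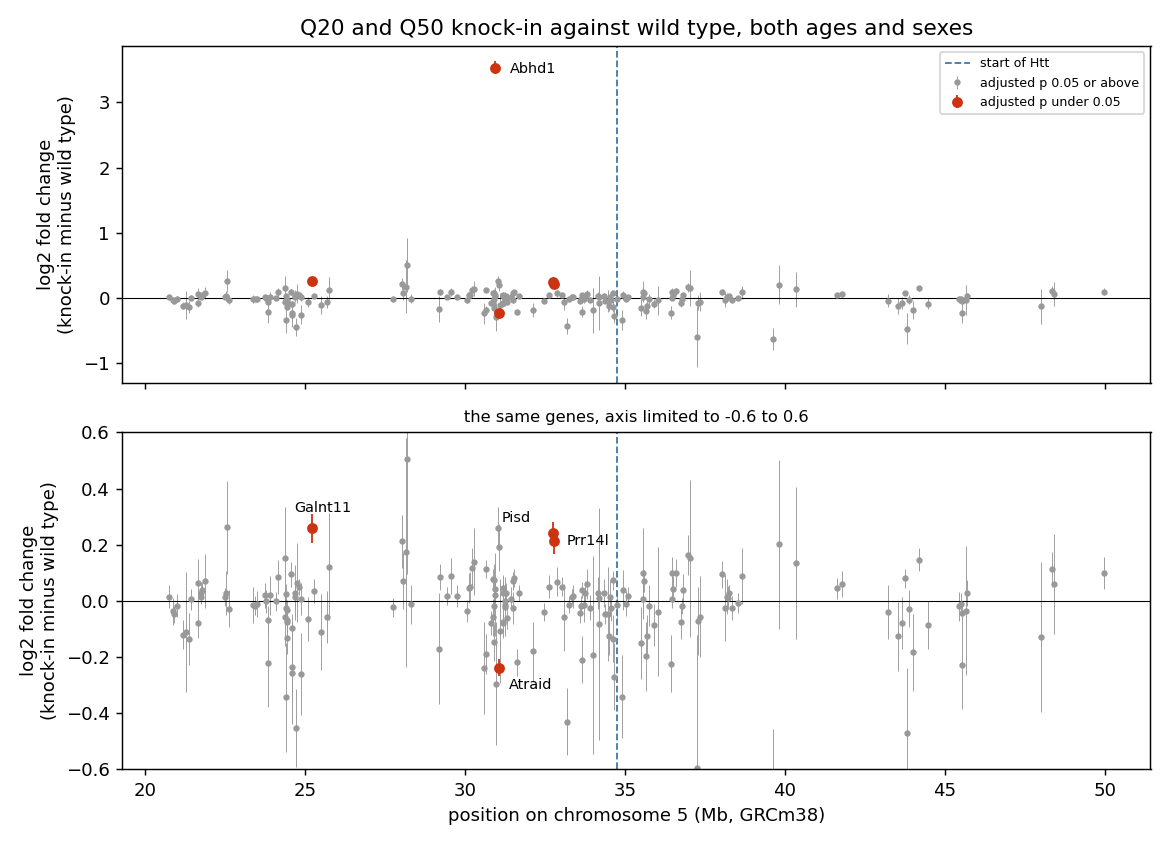
Log2 difference of Q20 and Q50 knock-in minus wild-type mice (vertical axis, bars ± SE) against position on chromosome 5 in Mb of GRCm38, in full above and limited to -0.6 to 0.6 below, for tested genes with an SE of at most 0.5. The coloured genes passed at adjusted p under 0.05, and the dashed line marks Htt.

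With the long repeats 1 gene in Q92 and 9 genes in Q140 mice passed against Q20 mice at 6 months. Gab1, an adaptor of receptor tyrosine kinases, was the 1 call for Q92 and was lower (13.5 ± 3.13 against 17.7 ± 3.03 CPM, -0.39 ± 0.08, adjusted p = 0.0394), with 1468 genes at an unadjusted p under 0.05. In Q140 mice 7 genes were higher and 2 lower, and 1892 genes had an unadjusted p under 0.05. Trim34a (10.8 ± 2.77 against 7.09 ± 1.10 CPM, 0.59 ± 0.12, adjusted p = 0.0364), Trim12c (0.59 ± 0.13, adjusted p = 0.0364) and Trim30d (0.57 ± 0.12, adjusted p = 0.0402) belong to a cluster of antiviral tripartite motif genes with near-identical copies, so their separate counts are uncertain. Galnt11 (0.48 ± 0.10) and the kinase Prkd2 (0.46 ± 0.10) were also higher (adjusted p = 0.0364 each). Nsun4 (-0.36 ± 0.08, adjusted p = 0.0402), a methyltransferase of mitochondrial ribosomal RNA, and Nbeal1 (-0.28 ± 0.06, adjusted p = 0.0416) were lower. The rare transcript Gm2445 (1.79 ± 0.34) and 1 gene identifier without a symbol (1.44 ± 0.31) made up the 9. None of the 29 interferon response genes passed over all genes and 21 rose adjusted over the list alone, led by Gbp3 (0.74 ± 0.18, adjusted p = 0.076), Tap1, Ifi44 (0.85 ± 0.21) and Usp18 (0.69 ± 0.17). Camera gave that list adjusted p = 7.4e-20 with the preset correlation and adjusted p = 0.0747 with an estimated correlation. Along the CAG length Caprin2 (0.72 ± 0.15, adjusted p = 0.0439), Trim34a (0.56 ± 0.11, adjusted p = 0.0366), the caspase gene Casp6 (0.45 ± 0.10, adjusted p = 0.0439) and Gm2445 (1.60 ± 0.31) rose. No gene fell there in edgeR, with 1848 at an unadjusted p under 0.05, while DESeq2 gave 94 calls (30 higher and 64 lower) and the fit with 3 surrogate variables 66 (23 higher and 43 lower). Along the same line 13 interferon genes rose adjusted over the list alone (adjusted p = 0.336 with an estimated correlation). The Gab1 call ended without replicate 1, 2 or 4 of the Q92 females, 1 or 4 of the Q92 males, 1 or 2 of the Q20 females or 1, 2 or 3 of the Q20 males, at differences of -0.41 to -0.34. The Q140 count was 0 without replicate 1 or 4 of the Q140 females or replicate 1 of the Q140 males. It was also 0 without replicate 1 or 2 of the Q20 females or 2 or 3 of the Q20 males. It was 125 without replicate 4 of the Q20 females. The trend gave 0 genes without replicate 1 or 4 of the Q140 females or 1 or 2 of the Q20 females. The same held without replicate 2 of the Q20 males or 2 or 4 of the Q50 males. The trend gave 104 genes without replicate 4 of the Q20 females. Against the wild types of both housings in place of Q20, 4 genes passed for Q92 and 395 for Q140 (223 higher and 172 lower), 6 of the latter among the 9. DESeq2 gave 13 and 87 calls against Q20, and the fit with 3 surrogate variables 0 and 85. With the lane as a covariate 0 genes passed for each by edgeR and for the trend, without a filter on low counts 0, 1 and 0, and in a separate fit per age 0, 3 and 3.

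At 10 months Q92 mice differed from Q20 mice in 419 genes, 261 higher and 158 lower, of which 84 changed at least 2-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 214 ± 88.1 against 55.1 ± 29.8 CPM (1.89 ± 0.42, adjusted p = 0.00709). The collagen gene Col1a1 (7.25 ± 1.90 against 2.51 ± 0.83 CPM, 1.53 ± 0.36, adjusted p = 0.013) and the tenascin gene Tnxb (20.9 ± 5.17 against 7.89 ± 2.23 CPM, 1.39 ± 0.27, adjusted p = 0.0034) were higher. So were the growth regulator Myc (5.57 ± 3.5 against 1.75 ± 0.574 CPM, 1.70 ± 0.35, adjusted p = 0.00516) and Cpxm1 (2.29 ± 0.57, adjusted p = 0.0175). The clock output factor Dbp (83.1 ± 29.8 against 34.9 ± 28.7 CPM, 1.33 ± 0.38, adjusted p = 0.0395), the mitotic kinase Wee1 (1.33 ± 0.29), the immunoglobulin gene Igha (1.53 ± 0.41), the B-cell linker Blnk (1.44 ± 0.35) and C330021F23Rik (1.43 ± 0.31) completed the 10 largest increases. Cdkn1a, which encodes the cell-cycle inhibitor p21, was lowest (1.42 ± 0.585 against 6.83 ± 5.93 CPM, -1.85 ± 0.37, adjusted p = 0.00361). Hsd17b6, a hydroxysteroid dehydrogenase (115 ± 60.6 against 271 ± 95.8 CPM, -1.42 ± 0.34, adjusted p = 0.0127), and the manganese exporter Slc30a10 (27.3 ± 6.42 against 63.7 ± 18.1 CPM, -1.11 ± 0.23, adjusted p = 0.0056) were also lower. Further decreases were those of Peg10 (-1.48 ± 0.38), Lhx6 (-1.11 ± 0.26), the choline kinase Chka (-1.10 ± 0.27) and Ugt1a9 (-0.95 ± 0.26), whose exons are shared with other Ugt1a genes, and of Gm2061, B230206H07Rik and Zdhhc2 (-1.33, -1.06 and -0.92).

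Cholesterol synthesis genes rose in the same comparison, 9 of 24 over all genes and 19 adjusted over the list alone, among them Fdps (0.89 ± 0.22), Mvk (0.90 ± 0.22) and Tm7sf2 (0.42 ± 0.11). Camera gave adjusted p = 3.43e-15 with the preset and adjusted p = 0.459 with an estimated correlation. Of 24 stellate cell and matrix markers 6 rose, 8 adjusted over the list alone, with Col6a1 (0.75 ± 0.18), Col1a2 (0.95 ± 0.24) and Col6a2 (0.87 ± 0.22) beside Col1a1 (adjusted p = 2.76e-07, and adjusted p = 0.524 with an estimated correlation). Of 18 p53 targets Cdkn1a and Eda2r (-1.13 ± 0.31, adjusted p = 0.0294) fell, 4 adjusted over the list alone, and this list held with an estimated correlation (adjusted p = 0.0396). Of the circadian genes Per3 (1.31 ± 0.32), Cry2 (0.43 ± 0.12) and Dbp were higher and Nfil3 (-0.90 ± 0.24) lower. The list did not pass (adjusted p = 0.0686). None of 20 lymphocyte markers passed over all genes and 3 passed adjusted over the list alone, with Jchain at 2.31 ± 0.69 (adjusted p = 0.0501). On the FPKM scale 411 genes were higher and 80 lower. Against the wild types of both housings in place of Q20, 6 genes passed, and without the libraries lacking an index 1 gene passed. The count was 82 without replicate 3 of the Q92 males, 171 without replicate 2 of the Q92 females, 148 and 164 without replicates 2 and 3 of the Q20 males, and 274, 262 and 227 without replicates 1, 3 and 4 of the Q20 females. It was 271 with the lane as a covariate, 224 without a filter and 206 in a separate fit per age. It rose to 1077 (571 higher and 506 lower) with 3 surrogate variables and to 893 (484 higher and 409 lower) without the 5 libraries with brain transcripts or a high mitochondrial share. None of these 5 is in the compared groups, so the latter rise can come only through the fit and scaling shared by all groups.

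Q140 mice at 10 months differed from Q20 mice in 71 genes, 39 higher and 32 lower, 22 of them at least 2-fold. Increases were seen for the dermatopontin gene Dpt (5.57 ± 1.43 against 2.33 ± 0.769 CPM, 1.29 ± 0.33, adjusted p = 0.0478), Tnxb (18.4 ± 6.69 against 7.89 ± 2.23 CPM, 1.24 ± 0.27, adjusted p = 0.0161) and the metalloproteinase Mmp2 (1.03 ± 0.26, adjusted p = 0.0432). They were joined by the protease Htra1 (0.93 ± 0.19, adjusted p = 0.0137), Ltbp3 (0.89 ± 0.21), Fbln5 (0.89 ± 0.21) and Podn (0.78 ± 0.18). Dsg1c (1.24 ± 0.27), the actin-severing gelsolin gene Gsn (0.87 ± 0.22) and Srebf1 (218 ± 59.3 against 126 ± 18.2 CPM, 0.79 ± 0.19, adjusted p = 0.0294), the regulator of fatty acid synthesis, were also higher. The transcription factor Zbtb16 stood at 7.93 ± 1.78 against 39.8 ± 22.0 CPM (-2.26 ± 0.57, adjusted p = 0.0476), and Cdkn1a at 1.44 ± 0.494 against 6.83 ± 5.93 CPM (-1.82 ± 0.37, adjusted p = 0.0137). The interleukin-1 receptor gene Il1r1 (-1.07 ± 0.25), Creb3l2 (22.4 ± 6.32 against 44.3 ± 8.55 CPM, -0.92 ± 0.18) and the sterol regulator Insig2 (-0.81 ± 0.17) were lower. Further decreases were those of Lhx6 (-1.19 ± 0.26), Tacc2 (-0.83 ± 0.19), Tmem200b (-1.03), Ablim3 (-0.70) and Zfhx2 (-0.67). Of 18 p53 targets 1 fell over all genes and 4 adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 0.0282). Of 24 matrix markers 1 rose over all genes and 6 adjusted over the list alone, and camera gave adjusted p = 0.486 with an estimated correlation. No circadian gene of 19 passed. Replicate 1 of the Q140 females at 10 months carried 169 CPM of 12 brain transcripts, against a median of 7.3 CPM over all libraries. Without it and the 4 other libraries with such transcripts or a high mitochondrial share 130 genes passed. The FPKM scale gave 119 higher and 12 lower. Against the wild types of both housings 3 genes passed, and without the libraries lacking an index 2. With the lane as a covariate 3 genes passed, and without a filter 37. DESeq2 gave 121 calls and the fit with 3 surrogate variables 147 (58 higher and 89 lower). The count was 24 and 15 without replicates 2 and 3 of the Q140 males, 11 without replicate 4 of the Q140 females, 34, 8 and 16 without replicates 1, 2 and 3 of the Q20 males, and 44, 31 and 37 without replicates 1, 3 and 4 of the Q20 females.

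Along the CAG length at 10 months 39 genes rose and 14 fell. Among those that rose were Dpt (1.29 ± 0.30, adjusted p = 0.0348), Mmp2 (1.04 ± 0.24), Tnxb (1.11 ± 0.25), Ltbp3 (0.91 ± 0.19, adjusted p = 0.0218) and Htra1 (0.89 ± 0.18, adjusted p = 0.0186). Htra3 (0.97) and Fbln5 (0.83) also rose, next to Capn6 (1.21 ± 0.30), Dsg1c (1.10 ± 0.25) and the glutathione peroxidase gene Gpx3 (0.82 ± 0.20). Of 24 matrix markers 1 rose over all genes and 6 adjusted over the list alone, and camera gave adjusted p = 0.531 with an estimated correlation. Cdkn1a (-1.41 ± 0.35, adjusted p = 0.0471), Creb3l2 (-0.83 ± 0.17, adjusted p = 0.0186), Insig2 (-0.66) and the carbonic anhydrase gene Car14 (-0.55) fell together with Htt. So did Leo1 (-0.53), the mitochondrial glutamate carrier Slc25a22 (-0.53), the calcium pump Atp2a2 (-0.48), Slc17a1 (-0.47) and Tmem263 (-0.42). Without Q20, the shortest repeat and a housing group of its own, no gene passed, Cdkn1a was at 0.31, Slc25a22 at 0.083 and Htt at -0.39, while 6 genes passed without Q92, 112 without Q50 and 362 without Q140. With the lane as a covariate 2 genes passed, without the libraries lacking an index 0, without a filter 19 and in a separate fit per age 18. With all lengths 1821 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 gave 120 calls (81 higher and 39 lower). The balance of directions moved with the processing, from 39 higher and 1 lower on log2(FPKM + 0.1) and 45 and 4 on log2(FPKM + 1) to 45 and 51 with 3 surrogate variables and 71 and 54 without the 5 libraries with brain transcripts or a high mitochondrial share. By edgeR 0 genes passed without replicate 4 of the Q20 females or replicate 3 of the Q140 males and 80 without replicate 3 of the Q140 females, and 13 of the 29 omissions of a library moved the count of 53 by more than 1.5 times.

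How much do the housing groups differ without any knock-in allele? At 6 months the wild types housed with Q50 mice had more Trp53inp1, a stress-induced regulator of autophagy, than those housed with Q20 mice (204 ± 37.3 against 86.1 ± 20.0 CPM, 1.25 ± 0.22, adjusted p = 0.00659). They also had more Slc45a3 (0.88 ± 0.18, adjusted p = 0.0378) and Hoxa5 (1.56 ± 0.32, adjusted p = 0.0378). No gene was lower, with 869 genes at an unadjusted p under 0.05 (DESeq2 gave 12 calls in both directions together). Of 25 cell cycle genes none fell over all genes and 18 fell adjusted over the list alone, with Mcm6 at -0.71 ± 0.16 and Mcm5 at -0.85 ± 0.22. The list held with an estimated correlation (adjusted p = 0.0346). Without replicate 1 of the wild-type females housed with Q20 0 genes passed, without replicate 1 of those housed with Q50 8, and 10 of 16 omissions moved the count by more than 1.5 times. The lane as a covariate and a separate fit per age gave 0 genes, and no filter gave 1.

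At 10 months the same wild types differed in 307 genes, 176 higher and 131 lower in mice housed with Q50, of which 48 changed at least 2-fold. Zbtb16 (7.35 ± 3.12 against 45.2 ± 25.1 CPM, -2.54 ± 0.53, adjusted p = 0.0043) and Cdkn1a (1.87 ± 1.15 against 6.54 ± 5.42 CPM, -1.84 ± 0.33, adjusted p = 0.00132) were lower. So were the DNA damage gene Gadd45g (-2.06 ± 0.54) and the pseudogene-like Gm20708 and Gm8355 (-2.23 ± 0.62 and -2.17 ± 0.61), which share sequence with other genes. Neither direction was stable, with Gm20708 at 0.06 without replicate 1 of the wild-type males housed with Q20 and Gm8355 at 0.072 with 3 surrogate variables. Aacs, which activates ketone bodies for lipid synthesis (89.5 ± 34.1 against 32.1 ± 15.5 CPM, 1.47 ± 0.35, adjusted p = 0.0146), and Mvd of the mevalonate pathway (33.5 ± 11.1 against 14.1 ± 6.49 CPM, 1.25 ± 0.30, adjusted p = 0.0145) were higher. Increases were also seen for Slc22a29 (1.25 ± 0.23, adjusted p = 0.00132), Hao2 (2.08 ± 0.60, adjusted p = 0.0499) and Cyp2c69 (1.31 ± 0.35). Of 24 cholesterol synthesis genes 8 rose over all genes and 23 adjusted over the list alone, Insig1 (0.89 ± 0.20) among them. Camera gave adjusted p = 7.77e-23 with the preset and adjusted p = 0.149 with an estimated correlation. Among 15 mitochondrial transcripts mt-Nd3 fell (-0.54 ± 0.15) and 8 fell adjusted over the list alone (adjusted p = 0.496 with an estimated correlation). Replicate 1 of the wild-type males housed with Q20 had 26.8% of its counts on the mitochondrial genome, against a median of 9.36%. Without the libraries lacking an index 92 genes passed, with the lane as a covariate 17, without a filter 171, in a separate fit per age 195, and by DESeq2 479. The count was 134, 565 and 569 without replicates 1, 3 and 4 of the wild-type males housed with Q20 and 169 and 181 without replicates 3 and 4 of the females. It was 197, 144 and 193 without replicates 2, 3 and 4 of the males housed with Q50 and 148 without replicate 2 of the females.

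Some of these genes had higher means in both Q20-housed groups than in all others at 10 months, while single libraries overlapped. Cdkn1a was at 6.83 ± 5.93 CPM in Q20 and 6.54 ± 5.42 in their wild types, against means of 1.25 to 1.87 CPM in the other 4 groups. Its lowest libraries there were at 1.56 and 1.67 CPM, and the highest library of the other groups was at 4.09 CPM. Zbtb16 was at 39.8 ± 22.0 and 45.2 ± 25.1 CPM against means of 7.35 to 15.9, with lowest libraries at 16.4 and 13.6 CPM against a highest of 42.1 CPM in Q92 mice. Col1a1 and Tnxb had their lowest means in Q20 mice (2.51 ± 0.83 and 7.89 ± 2.23 CPM). The differences of Q20 from its wild types (4.97 ± 2.18 and 14.2 ± 5.58 CPM) did not pass (Col1a1 -0.995 ± 0.35, adjusted p = 0.298; Tnxb -0.87 ± 0.26, adjusted p = 0.243). These genes were set side by side after their values were seen.

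**Figure D3:**
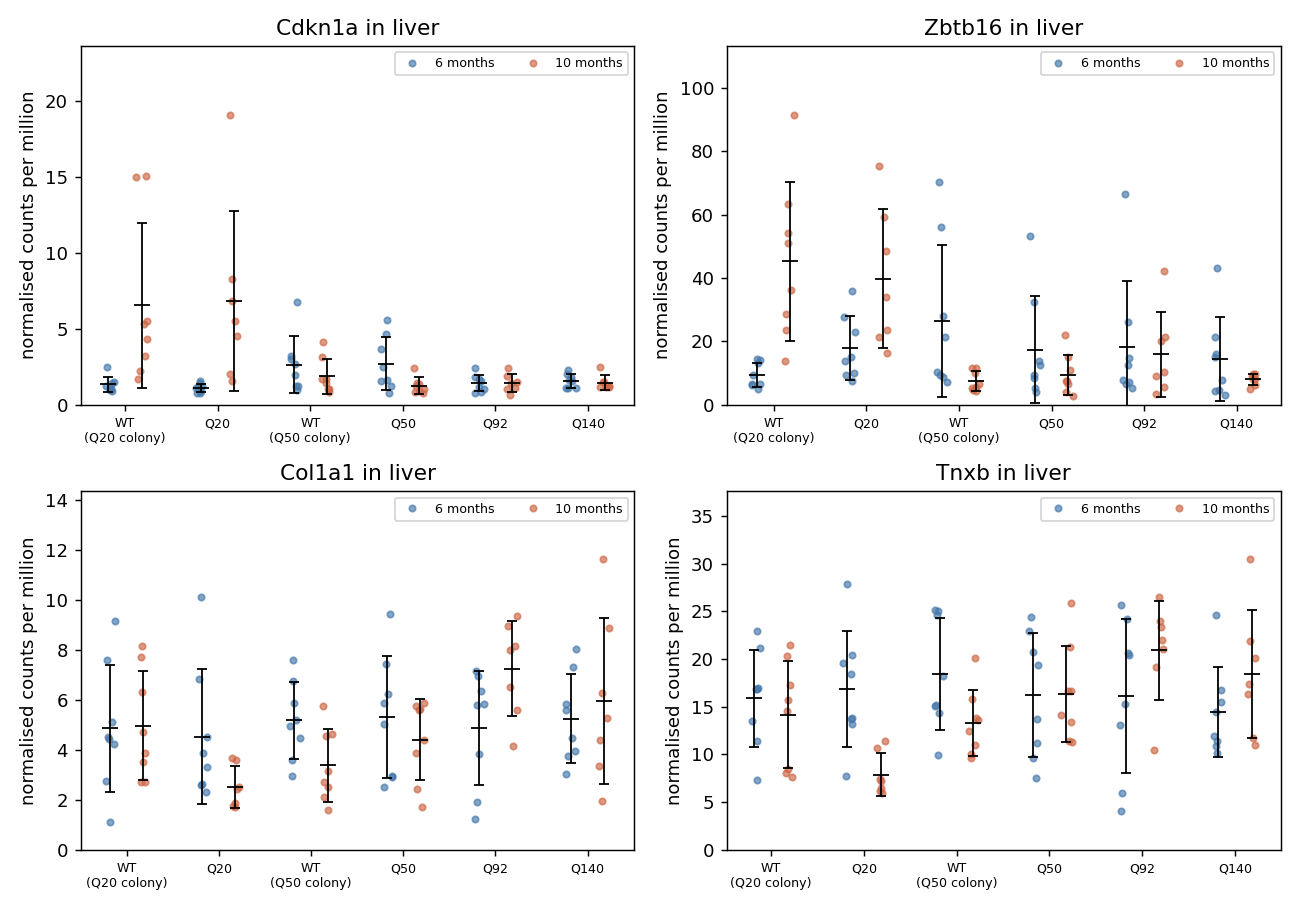
Cdkn1a, Zbtb16, Col1a1 and Tnxb in CPM (vertical axes) by genotype and housing at 6 and 10 months; points are libraries, and bars are the mean with 1 SD. At 10 months Q20 mice and the wild types housed with them have higher means than the other groups in Cdkn1a and Zbtb16, while Col1a1 and Tnxb have their lowest means in Q20 mice.

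Wild-type livers of 6 and 10 months differed in 2443 genes, 1359 higher and 1084 lower at 10 months. Of these, 274 differed at least 2-fold. All libraries of 6 months belong to one number series in the labels and all of 10 months to another. Age and a technical difference between the series therefore cannot be separated here, and this holds for all genes and lists below. Male-biased liver genes declined, with 10 of 21 lower over all genes and 16 adjusted over the list alone (adjusted p = 0.258 with an estimated correlation). The organic anion carrier Slco1a1 (-2.10 ± 0.33, adjusted p = 3.56e-06), the serpin gene Serpina1e (-2.02 ± 0.33, adjusted p = 8.46e-06) and the steroid dehydrogenase gene Hsd3b5 (-1.37 ± 0.38, adjusted p = 0.00932) were among the 10 largest decreases. The signal recognition RNAs Rn7s1 (-2.58 ± 0.53) and Rn7s2 (-2.46 ± 0.57), near-identical copies with uncertain counts, also fell. The others were the glycogen regulator Ppp1r3g (-1.75 ± 0.51), Gm11175 (-1.48), Gdap10 (-1.40 ± 0.24), Cib3 (-1.39) and the immediate-early gene Nr4a1 (-1.38 ± 0.42). The immunoglobulin genes Ighm (1.81 ± 0.48, adjusted p = 0.00686) and Igkv3-5 (2.81 ± 0.96) rose, as did the female-biased cytochrome gene Cyp2b9 (2.03 ± 0.47, adjusted p = 0.00163). The other 7 of the 10 largest increases were the pseudogenes or predicted genes Gm5537 (2.65), Gm14303 (2.23), Gm8355 (2.19), Gm9845 (2.0), Gm15401 (2.0 ± 0.15, adjusted p = 2.97e-17), Gm20721 (1.81) and Rpl17-ps8 (1.8). Their reads cannot be told from those of their parent genes with certainty. Of 18 p53 targets 4 rose and 1 fell (adjusted p = 0.285 with the preset and 0.557 with an estimated correlation), with increases of Eda2r (1.02 ± 0.20, adjusted p = 0.00028), Cdkn1a (0.96 ± 0.24), Fas (0.33 ± 0.07) and Ccng1 (0.20 ± 0.05). The mean of Cdkn1a went from 1.32 to 6.54 CPM in wild types housed with Q20 and from 2.62 to 1.87 CPM in those housed with Q50 mice. Of 18 genes of the repeat instability list 4 rose and none fell (adjusted p = 0.0315 with the preset and 0.557 with an estimated correlation). Htt did not pass with age (0.09 ± 0.07, adjusted p = 0.405), but it did without the libraries lacking an index (0.21). The FPKM scale gave 1629 higher and 670 lower genes.

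Sex was the largest contrast, with 7100 genes, 3537 higher and 3563 lower in wild-type males, of which 930 differed at least 2-fold. The Y-linked genes Ddx3y (79.0 ± 7.91 CPM in males against 0.00996 ± 0.0163 in females), Eif2s3y (54.8 against 0.0114), Kdm5d (19.0 against 0.00309) and Uty (17.2 against 0.00494) and the X-inactivation gene Xist (0.299 against 623 ± 131 CPM) separated the libraries by their labelled sex. In males the fatty acid hydroxylase genes Cyp4a12a (370 ± 148 against 0.167 ± 0.116 CPM) and Cyp4a12b (113 ± 48.8 against 0.0537) were higher. So were the urinary protein gene Mup7 (14870 ± 9360 against 20.6 ± 9.32), Hsd3b5 (153 ± 55.6 against 0.368), Moxd1 (8.62 ± 12.5 against 0.0078) and Obp2a (2.31 against 0.00348). In females the sulfotransferases Sult2a1 (0.0835 against 292 ± 146 CPM), Sult2a2 (0.0639 against 262 ± 109) and Sult3a1 (0.0691 against 99.9), with Sult2a3 and Sult2a5, were higher. The same held for the cytochromes Cyp2b13 (0.101 against 309 ± 77.3) and Cyp2a4 (0.825 against 842 ± 324) and for A1bg (0.262 against 728 ± 633). The Cyp4a12, Sult2a, Mup and Cyp2 genes have close copies, so the values of single members are uncertain. All 21 male-biased and all 23 female-biased genes of the fixed lists differed in the named direction, and 6 of 8 adipocyte markers were higher in males. These lists held with an estimated correlation (adjusted p = 7.2e-08, 3.77e-10 and 0.0171). Proteasome genes were higher in males (31 of 32, led by Psmc4 at 0.52 ± 0.05; adjusted p = 0.217 with an estimated correlation). Of 29 interferon genes 21 were lower and 1 was higher (Gbp3 -2.04 ± 0.13; adjusted p = 0.217 with an estimated correlation). Htt was higher in males (0.29 ± 0.07, adjusted p = 0.000322), which did not hold on the FPKM scale (0.11) or without the libraries lacking an index (0.17). On the FPKM scale the median over all genes moved to -0.14, from 0.00, and 1471 genes were higher and 6308 lower.

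Whether the difference between Q140 and Q20 mice depended on sex was tested as an interaction, and 20 genes passed, 9 higher and 11 lower in males relative to females. Clock-controlled genes were lower, with Ciart (-3.64 ± 0.82, adjusted p = 0.032), Usp2 (-3.02 ± 0.66), Dbp (-2.28 ± 0.52), Per3 (-2.12 ± 0.44) and Wee1 (-1.81 ± 0.40). Of 19 circadian genes 5 fell over all genes, Tef among them (-1.13 ± 0.25). Adjusted over the list alone 3 rose and 10 fell, and the list held with an estimated correlation (adjusted p = 0.0105). Tubb2a (1.69 ± 0.37, adjusted p = 0.0268), Slc30a10 (1.45 ± 0.32), the mitochondrial chaperone gene Clpx (1.43 ± 0.29), Leo1 (0.77) and Ccdc162 (0.74) were higher. The count was 1 without replicate 4 of the Q140 females at 10 months and 38 without replicate 4 of the Q20 males at 6 months, and 16 of 30 omissions moved it by more than 1.5 times. It was 0 with the lane as a covariate, 1 without the libraries lacking an index and 7 without the 5 libraries with brain transcripts or a high mitochondrial share, against 54 by DESeq2 and 74 with 3 surrogate variables.

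For the dependence on age 11 genes passed, 4 with a higher and 7 with a lower Q140 against Q20 difference at 10 than at 6 months. Cdkn1a (-2.33 ± 0.50, adjusted p = 0.0436), the antisense transcript B430119L08Rik (-1.52), Slc25a22 (-0.85 ± 0.18), the acetyl-CoA acetyltransferase gene Acat3 (-0.48) and Gpr107 (-0.38) were lower, with the rare transcripts Gm2445 (-2.33) and Serpinb1c (-5.48). Rab34, a small GTPase (0.87 ± 0.18, adjusted p = 0.0426), the deubiquitinase gene Mindy4 (0.83), Erc2 (0.69) and Tmem63b (0.45) were higher. Of 29 interferon genes 12 fell adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). RLE scaling gave 8 higher and 7 lower, and the FPKM scale 9 and 3. The count was 0 without replicate 4 of the Q140 females and 18 without replicate 4 of the Q20 females at 6 months, and 22 of 30 omissions moved it by more than 1.5 times. It was 0 with the lane as a covariate, without a filter and without the libraries lacking an index, against 42 by DESeq2, 84 with 3 surrogate variables and 21 without the 5 libraries with brain transcripts or a high mitochondrial share.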

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

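The tests of a chromosome 5 segment, of the repeat length, of the colony difference, of the omitted libraries and of the brain lists were chosen only after the results they concern were seen; the splits of the samples, the test of Preb and the test of low transcripts were written before theirs.

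Some libraries stood far from the others of their group of 4 by Dixon's test, which by chance singles out about 1 in 20 groups. Over 6 measures 11 of 126 groups held such a library, where 6.3 are to be awaited by chance. One of these measures is the sum of brain transcripts, whose genes were chosen after library values were seen. The libraries it singles out are therefore no fair part of this comparison with chance. Abhd1 was at 23.7 CPM in replicate 3 of the Q50 males at 6 months and at 3.57 CPM in replicate 1 of the wild-type males housed with Q20 at 10 months, and Atraid at 39.6 CPM in replicate 1 of the Q50 males at 6 months. Htt was at 31.3 CPM in replicate 1 of the Q140 males at 6 months, at 32.4 CPM in replicate 1 of the wild-type males housed with Q20 at 10 months, and at 18.8 CPM in replicate 3 of the wild-type females housed with Q50 at 6 months. The mitochondrial share of replicate 1 of the wild-type males housed with Q20 at 10 months was 26.8%. The 12 brain transcripts summed to 169 CPM in replicate 1 of the Q140 females at 10 months, to 46.8 CPM in replicate 4 of the Q140 males at 6 months, to 46.0 CPM in replicate 1 of the Q20 males at 6 months and to 47.3 CPM in replicate 1 of the wild-type males housed with Q20 at 10 months.

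The Q140 against Q20 difference depended on sex, by an interaction term, in 20 genes. It was higher in males than in females for Tubb2a (1.69), Slc30a10 (1.45), Clpx (1.43), Leo1 (0.77) and Ccdc162 (0.74), and lower in males for Ciart (-3.64), Usp2 (-3.02), Dbp (-2.28), Per3 (-2.12) and Wee1 (-1.81). It depended on age in 11 genes, higher at 10 months for Rab34 (0.87), Mindy4 (0.83), Erc2 (0.69) and Tmem63b (0.45), and lower for Cdkn1a (-2.33), B430119L08Rik (-1.52), Slc25a22 (-0.85), Acat3 (-0.48), Gpr107 (-0.38), Gm2445 (-2.33) and Serpinb1c (-5.48). No cause of these was tested beyond the splits of the samples.

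Each count of genes was set against 100 splits of the same samples into groups of the same sizes, the real split included. Chance was not excluded for the counts of Q20 against wild type at 6 months (13 splits gave as many; real 1, highest other 3) and 10 months (24 splits; 1 and 439), of Q50 against wild type at 6 months (14 splits; 1 and 241) and of Q92 against Q20 at 6 months (14 splits; 1 and 55). A share of splits under 0.05, not adjusted over the 16 comparisons, made chance unlikely for the others. These were Q50 against wild type at 10 months (3 splits, 2 and 2), Q140 against Q20 at 6 months (2 splits, 9 and 11) and 10 months (3 splits, 71 and 214), and Q92 against Q20 at 10 months (1 split, 419 and 95). The CAG length trend at 6 months (1 split, 4 and 2) and 10 months (2 splits, 53 and 55) was among them. So were the wild types of both housings at 6 months (2 splits, 3 and 4) and 10 months (1 split, 307 and 76). Age (1 split, 2443 and 892), sex (1 split, 7100 and 4559), the dependence on sex (3 splits, 20 and 56) and the dependence on age (1 split, 11 and 8) completed them. For Q140 against Q20 at each age, the trend at 10 months, the wild types at 6 months and the dependence on sex another split gave more genes than the real one. Splits cannot separate age from the number series of the libraries. Splits with several times the real count, as for Q20 against wild type at each age, Q50 against wild type and Q92 against Q20 at 6 months, Q140 against Q20 at 10 months and the dependence on sex, point to a structure of the samples, and what it is was not tested.

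Abhd1 was higher in knock-in mice of every repeat length. Wild types are not part of the CAG length trend, so a step between them and Q20 is not bounded by it. A linear change from Q20 to Q140 was excluded as the source. The largest 95% bound of the Abhd1 change along the trend was 0.47, against differences of 3.42 to 3.80 from wild type. Reads moved to it from the overlapping gene Preb were excluded as well, since Preb stood at 85.2 CPM in knock-in and 82.6 CPM in wild-type mice (log2 difference 0.04, 95% interval -0.029 to 0.115), and a loss of the 19.5 CPM gained by Abhd1 would have put it at -0.389. New transcripts across the overlap whose reads are all given to Abhd1 are not bounded by this. A candidate explanation is a segment of chromosome 5 inherited with the allele. The odds ratio of 3.89 for unadjusted p under 0.05 within 10 Mb of Htt goes with it, though that ratio counts neighbouring genes as independent. Galnt11, 9.54 Mb from Htt, had a mean at the level of wild types in Q20 but a higher one in Q50, Q92 and Q140 mice, and may mark segments of different length. The lowest Q92 and Q140 libraries were at 10.1 and 10.2 CPM and the lowest Q50 library at 13.5 CPM, against wild-type means of 11.4 and 11.3 CPM. A strain variant that alters how reads map, and an effect of the allele on its neighbours, were not tested.

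The genes that differ between Q92 and Q20 mice at 10 months were weighed next. Of the called genes 77.1% had the same sign in the comparison of the wild types of both housings, which shares no library with it (p = 0.041 over 1000 splits of the wild types, median 49.6%, maximum 92.1%), while the correlation across these genes was 0.266 (p = 0.255). A colony difference present without the allele may therefore account for part of the list. Brain transcripts in a compared library were neither excluded nor shown to account for it. Replicate 1 of the Q20 females had the most (16.69 CPM, or 2.29 times the median of all libraries), and 274 genes passed without it, while 6 of the 13 other omissions of a compared library gave fewer (82 to 511, median 321). Mitochondrial shares of the compared libraries ran from 7.59% to 10.76%. Without the 4 libraries of these groups that lack an index 2 genes passed, and 12 of 100 choices of 4 libraries gave as few (others 0 to 588, median 51), so the index cannot be told apart from the loss of libraries; an effect of the repeat length itself stays open, since the design joins it with housing.

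Transcripts of brain appeared in 4 liver libraries. A further list of 8 striatal genes rose in each, the lowest ratio to the median of other libraries being 3.42, and without Adora2a, which liver expresses, the ratios were 25.9 to 116. Genes of cortex, hippocampus and cerebellum, leaving out Prox1, which liver expresses, rose by 2.14 times at most. Their median in the other libraries was 0.87 CPM, against 0.11 CPM for the striatal list without Adora2a. Ratios over such unlike baselines cannot exclude a brain region without striatal neurons as the source. Over 27100 other genes with a median of at most 1 CPM the sum rose by 1.8 times at most, and 1.58 times in the highest library outside the 4. A general rise of low transcripts by as large a factor as the striatal list was therefore not seen, while a smaller one was not excluded. RNA or reads of brain tissue with striatum in these libraries is a candidate source, and where they came in was not tested. Pan-brain genes low in liver rose 2.67 to 10.99 times, but from a median of 1 CPM, so this ratio too cannot be set against that of the striatal list. In CPM the pan-brain and striatal lists stood at 10.95 and 12.59 in the Q140 female and 2.66 and 2.81 in the Q140 male. They stood at 3.17 and 3.36 in the Q20 male and 4.66 and 2.99 in the wild-type male. The list of cortex, hippocampus and cerebellum was at 1.87, 1.07, 0.82 and 1.22 CPM in these libraries, and at up to 1.46 CPM in the others.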

How the results depend on the processing

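The omission of 5 libraries with brain transcripts or a high mitochondrial share, the trend over 3 of the 4 CAG lengths and the coding of the lane were chosen only after the data or results were seen; the other alternatives were planned. Abhd1 stayed past the threshold in all 4 comparisons of Q20 and Q50 with wild type under every alternative and omission run that kept wild types as the reference (Q50 against Q20, where both carry the allele, shared no call at 6 months), and the counts for age and sex stayed within 1.5 times of 2443 and 7100 under all alternatives run. In what follows, values without a name are numbers of genes passing, and the cause was not tested unless a sentence names one. DESeq2 gave 6 (Q20 against wild type, 6 months), 13 (Q92 against Q20, 6 months), 87 (Q140 against Q20, 6 months), 94 (trend, 6 months), 12 (wild types, 6 months), 3 (Q20 against wild type, 10 months), 121 (Q140, 10 months), 120 (trend, 10 months), 479 (wild types, 10 months), 54 (dependence on sex) and 42 (dependence on age), and called Htt along the trend at 6 months (-0.34). RLE factors gave 11 for the trend at 6 months. With 3 surrogate variables the counts were 0 (Q92), 85 (Q140) and 66 (trend) at 6 months, 1077, 147 and 96 at 10 months, 74 for the dependence on sex and 84 for that on age; Htt was called for Q140 at 6 months (-0.33), the trend at 6 months (-0.32) and Q92 at 10 months (-0.35), and changed sign for Q20 at 10 months (-0.037), as Gm8355 did between wild types at 10 months (0.072). Without a filter on low counts, which tests more genes, they were 0 (Q92), 1 (Q140), 0 (trend) and 1 (wild types) at 6 months, 224, 37, 19 and 171 at 10 months, and 0 for the dependence on age. A separate fit per age, with fewer libraries for the spread, gave 0 (Q92), 3 (Q140) and 0 (wild types) at 6 months and 206 (Q92), 18 (trend) and 195 (wild types) at 10 months. The lane as a covariate gave 0 for Q92, Q140, trend and wild types at 6 months, 271 (Q92), 3 (Q140), 2 (trend) and 17 (wild types) at 10 months, and 0 for both dependences. That covariate pooled the libraries lacking an index as a level of their own, so it is not separate from their omission.

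On log2(FPKM + 0.1) the counts were 0 (Q92, 6 months), 2 (Q20 against wild type, 10 months) and 131 (Q140, 10 months); Htt was at -0.083 (Q20 against wild type, 10 months), -0.41 (Q140, 10 months), -0.36 (trend, 10 months) and 0.11 (sex), the last 3 no longer past the threshold, and the proteasome list changed direction for Q140 at 10 months (adjusted p = 0.98). On log2(FPKM + 1) they were 0 (Q92), 5 (Q140) and 0 (trend) at 6 months, 2 (Q20 against wild type) and 107 (Q140) at 10 months, with Htt at -0.062, -0.30, -0.26 and 0.085 in the same comparisons. FPKM without a filter gave 0 (Q92), 0 (trend) and 1 (wild types) at 6 months, 4 (Q20 against wild type) and 200 (wild types) at 10 months and 0 for the dependence on sex, with Htt as with the filter (-0.083, -0.41, -0.36 and 0.11). Without the 16 libraries lacking an index, which leaves fewer samples, the counts were 2 (Q20 against wild type), 0 (Q92), 18 (Q140) and 0 (trend) at 6 months, 1 (Q92), 2 (Q140), 0 (trend) and 92 (wild types) at 10 months, 1 for the dependence on sex and 0 for that on age. Htt was then at -0.38 (Q140, 10 months), -0.35 (trend, 10 months) and 0.17 (sex), all no longer past the threshold, at 0.21 with age, now past it, and changed sign for Q20 against wild type (-0.005) and for the wild types at 10 months (0.014); the lymphocyte list of Q140 at 10 months (adjusted p = 0.925) and the PPAR list of the wild types at 10 months (adjusted p = 0.661) changed direction. Without the 5 libraries with brain transcripts or a high mitochondrial share the counts were 3 (Q20 against wild type), 0 (Q92), 45 (Q140) and 12 (wild types) at 6 months, 2 (Q20 against wild type), 893 (Q92), 130 (Q140), 125 (trend) and 195 (wild types) at 10 months, 7 for the dependence on sex and 21 for that on age; Htt was called for Q92 at 10 months (-0.31), and Gm20708 changed sign between the wild types at 10 months (0.059).

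Against the wild types of both housings 3 genes passed for Q20 at 6 and 14 at 10 months, 4 and 6 for Q92 and 395 and 3 for Q140; Q50 against Q20 gave 88 and 50. Of the 6 genes of Q92 at 10 months 4 were among the 419, and of the 395 of Q140 at 6 months (223 higher, 172 lower) 6 were among the 9. The trend at 6 months had 119 genes without Q20, 28 without Q92 and 0 without Q140; at 10 months it had 0 without Q20, with Htt at -0.39 and no longer past the threshold and Cdkn1a (0.31) and Slc25a22 (0.083) reversed, 6 without Q92, 362 without Q140, with Htt at -0.50 and no longer past it, and 112 without Q50. The replicate number of the labels as a replicate block gave 0 for Q92 at 6 months and moved no other count by more than 1.5 times; samples of the same number did not deviate together (mean correlation 0.0066, against -0.0018 for other numbers, and 0 of 20 pairs of groups had every correlation above 0.1), so the numbers do not pair the samples.

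Leaving out 1 library at a time gave 1 to 2 genes for Q20 against wild type at 6 months, 0 to 2 for Q92, 0 to 125 for Q140, 0 to 104 for the trend and 0 to 8 for the wild types at 6 months, and 1 to 11 for Q20 against wild type, 82 to 511 for Q92, 8 to 96 for Q140, 0 to 80 for the trend and 134 to 569 for the wild types at 10 months. The dependence on sex had 1 to 38 and that on age 0 to 18 genes, age 1772 to 2828 and sex 6749 to 7577. Htt ranged from -0.007 to 0.13 between the wild types at 6 months, from -0.025 to 0.065 for Q20 against wild type at 10 months and from -0.54 to -0.42 for the trend at 10 months, and Gm20708 from -2.43 to 0.06 between the wild types at 10 months. Of 155 calls of named genes, DESeq2 and RLE factors kept 153 each, surrogate variables 145, the block 139, the omission of 5 libraries 135, no filter 93, the lane 59 and the omission of libraries without an index 56, and FPKM with 0.1 added kept 115 of 154. Over all omissions of 1 library these calls were kept 2638 times, lost 1032 times and reversed 1 time. Of 212 list calls 8 held with an estimated correlation and 42 under fry, and 208 under RLE factors, 184 on FPKM and 170 with surrogate variables. What depth limits was not tested, and the rare transcripts Gm2445 and Serpinb1c rest on few counts (means of 0.187 and 0.0655 CPM).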

Other observations

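The tests in this part were chosen only after the values were seen, apart from the lists of genes, which were fixed in advance.

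Liver zonation, protein folding and immune genes differed by sex in wild types. Of 17 pericentral hepatocyte genes 12 were lower and 1 higher in males, with Notum at -0.76 ± 0.08 (edgeR; camera adjusted p = 0.318 with an estimated correlation). Of 24 genes of the unfolded protein response 18 were higher (adjusted p = 0.318 with an estimated correlation), as were 13 of 15 mitochondrial transcripts (adjusted p = 0.383 with an estimated correlation). Macrophage markers were lower for 16 of 18 and lymphocyte markers for 18 of 20 with 1 higher (adjusted p = 0.382 and 0.383 with an estimated correlation), and of 19 circadian genes 4 were higher and 12 lower.

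Pseudogenes stood out with age in wild types. Of 673 tested pseudogenes 212 were higher and 16 lower at 10 months, against 1147 higher and 1068 lower among other genes (Fisher's exact test, two-sided p = 6.22e-39). That test counts genes as independent, though pseudogene reads cannot be told from those of parent genes with certainty. Its p therefore does not measure the spread between libraries. Age is also joined here with the number series of the libraries, so a technical source was not excluded. Mitochondrial electron transport genes fell for 8 of 54 (adjusted p = 0.557 with an estimated correlation), and heat shock genes for 5 of 22, with Hspa1b at -1.13 ± 0.30. Interferon genes rose for 6 of 29 (adjusted p = 0.607 with an estimated correlation).

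Abhd1 was at 2.39 CPM in replicate 1 of the Q50 females at 6 months, below the highest wild-type library at 3.57 CPM. Galnt11 was at 14.6 CPM in that library, the lowest of the 4 Q50 females of that age, above the highest of the 16 wild types housed with Q50 at 13.4 CPM and below the highest of those housed with Q20 at 16.2 CPM. At 10 months 48 genes passed both between Q92 and Q20 and between the wild types of both housings, 34 higher in both and 12 lower in both, where 2.85 and 1.28 would be shared by independent lists. That expectation takes the genes as independent, which they are not. In splits of the wild types up to 92.1% of the genes called for Q92 shared their sign, so the excess does not measure chance between libraries.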
